A study of Mus musculus with 24 samples.

How the data were processed

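RNA bound to tagged ribosomes was sequenced from the dentate gyrus, the part of the hippocampus in which neurons are born in adult life. Per the labels' protocols, the mice carried a Cre recombinase that tamoxifen switches on in cells expressing Nestin, a filament protein of neural stem cells. After recombination the ribosomal protein Rpl22 gains a haemagglutinin (HA) tag, so that ribosomes of the recombined cells and of their descendants can be precipitated together with the RNA they carry (RiboTag). Per the labels, the animals were female C57BL6 mice, 12 libraries hold RNA from the precipitate (IP), assigned there to immature neurons, and 12 hold RNA of the dentate gyrus (input). Running mice had a wheel that turned and sedentary mice an identical wheel that was blocked, and the treatment time was 11, 18 or 27 days. The libraries were made with the SMARTer Stranded Total RNA-Seq Kit, per the labels' protocols.

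Per the submitters' processing notes, the tool was RSEM and the genome build mm10. The RSEM version, the aligner, the annotation and the strand setting are not given in the sources used here, so genes that overlap or lie antisense to each other could not be told apart with certainty. The authors deposited 1 table of TPM (transcripts as a share of a fixed total) with 23306 genes and 24 libraries, and each column sums to 1000000. TPM keeps no read depth. The depth per library is therefore unknown, no counting interval was computed, and the precision of each value rests on the spread between libraries. Of the gene names, 21658 were found in GENCODE M21, whose assembly GRCm38 is the mm10 build and which gave all coordinates. In 27 gene names a symbol had been turned into a date, and these genes were not named. A name occurred more than once for 2 entries. A TPM of exactly 0 is given as listed at 0, because the table does not show whether it stands for no reads or for a failed estimate.

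Each library was placed by its labels in 1 of 12 groups (fraction, activity, day) of 2 libraries. Libraries carry the letters a and b at day 11, c and d at day 18, and e and f at day 27. The labels do not say how many mice went into a library, nor that libraries of a group came from separate mice, so the p-values measure the spread between these samples, which may be technical. Gene tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust) on log2(TPM + 1). All fold changes are on this log2(TPM + 1) scale, which understates the change of low genes. Genes with a mean TPM of at least 1 over the libraries of a fit were tested, which left 19507 genes in the fit of all 24 libraries, 17282 in the 12 IP libraries and 20462 in the 12 input libraries. Contrasts were taken between group means: IP against input, running against sedentary (as the mean of the 3 days and within each day), day against day (as the mean of both activities), the difference of the running effect between days (F test), and the running effect in IP minus that in input. P-values were adjusted by the Benjamini-Hochberg method over the genes of a contrast, with a threshold of 0.05 on the adjusted p. All adjusted p-values of genes come from limma, and all its gene tests are two-sided except the F test, which has no direction.

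The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The lists were 35 sets of genes, covering cell types of the hippocampus and its surroundings, synaptic and developmental functions, energy and protein metabolism, and stress, clock and hormone responses. Of their 573 members entered by name, 9 had no entry in the table. A list with at least 5 tested members was compared with all other genes by limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera was run again with an estimated correlation, and fry tested whether a list moved one way. The level of a list in a library was its mean log2(TPM + 1), compared by a two-sided exact permutation test over 216 relabellings within days for running (smallest possible p = 0.00926) and over 70 relabellings for 4 against 4 libraries (smallest possible p = 0.0286). A comparison of 2 against 2 libraries cannot give a two-sided exact permutation p below 0.333. Named genes were the 10 largest changes in each direction among genes past the threshold, with a mean TPM of at least 5 in the higher arm and no overlap between the arms. Where fewer than 5 genes passed in a direction, the 5 genes of lowest unadjusted p were named instead. Up to 4 members of a list with the lowest unadjusted p were named where the list is described, and Rpl22, Dcx, Gfap, Mbp and Calb1 were named in the comparison of IP with input in any case. Gene models without a proper name were only counted. Xist was named for running in the IP and for IP against input outside this rule, after its values were seen. Some genes taken by the rule are not reported here.

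The fits were tested on simulated data in which known genes were changed by known folds. Each gene had its own independent spread around 1 mean, with no effect shared by a library, letter or day. The shares below may therefore be higher than those in the real libraries, where such effects occur. For the first contrast below, 10 of 155 calls were of unchanged genes. For running against sedentary in the IP (mean of days, 16951 genes), 50.0% of genes changed 1.5-fold, 81.5% of those changed 2-fold and 96.7% of those changed 4-fold were recovered. For running against sedentary in the IP at day 27 (17015 genes) these shares were 1.52%, 42.4% and 83.1%, for day 27 against day 11 in the IP (16965 genes) 34.8%, 65.2% and 93.7%, and for running in the input (mean of days, 19710 genes) 21.3%, 73.0% and 90.9%.

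The alternatives were a pseudocount of 0.1 or 5, no filter or a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, totals without 762 structural RNA genes, array weights, eBayes without the robust option, the library letter as a block, each library left out in turn, fits of the 4 libraries of a day alone, day as an additive term, and IP values taken relative to the input library of the same code. Alternatives added after the data were seen were the level of 1102 olfactory receptor genes as a covariate, IP against input without the day 18 libraries, the IP without both day 11 libraries of letter a, running in the IP from days 18 and 27 alone, and the list tests with each library code left out, with quantile normalization and without the structural RNA genes. Proteins translated from GENCODE M21 coding sequences were searched for stretches of the HA tag with Python 3.11.15, and the plots were drawn with matplotlib 3.10.9.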

Results

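RNA was measured in 24 libraries from the dentate gyrus of female mice that ran freely on a wheel or lived with a blocked one. In 12 libraries the RNA came off ribosomes precipitated by the HA tag (IP), and in 12 it came from the tissue without precipitation (input). Mice of each activity were taken after 11, 18 or 27 days, with 2 libraries for every combination of fraction, activity and day. Values are TPM, so the read depth of the libraries is unknown. The median gene stood at 8.20 ± 0.881 TPM in the IP and at 6.50 ± 1.62 TPM in the input (mean ± SD, n = 12 libraries each). Rpph1, the RNA component of ribonuclease P, took 6.96 ± 3.50% of the TPM of an IP library and 3.78 ± 1.06% of an input library. Gm20594, a nuclear copy of mitochondrial ribosomal RNA, took 2.004 ± 0.274% and 9.15 ± 1.499%. The nuclear RNA Malat1 took 3.55 ± 0.411% and 1.02 ± 0.279%. The running IP library a of day 11 held 17.4% Rpph1 and had the lowest median gene of the IP, at 6.20 TPM. The other IP libraries held 4.58 to 9.16% Rpph1.

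Olfactory receptor genes, which are used by sensory neurons of the nose, served as a measure of background in each library. Their mean in the input was 1.09 ± 0.999 TPM at day 11, 7.36 ± 2.09 TPM at day 18 and 2.61 ± 0.908 TPM at day 27 (SD, n = 4 each). At day 11 the sedentary input library a held 2.58 TPM and the other 3 held 0.709, 0.518 and 0.542 TPM. In the IP it was 0.944 ± 0.380, 1.08 ± 0.122 and 1.62 ± 0.432 TPM on the same days. The first principal component took 69.8% of the variance of the input libraries and 26.8% of that of the IP libraries. It correlated with the olfactory receptor level at 0.996 in the input and 0.811 in the IP, in absolute value. Both IP libraries of day 11 with the letter a lay apart on the IP component, at −49.7 and −42.1, against −6.91 to 39.7 for the other 10. They also held the lowest olfactory receptor means of the IP, 0.709 TPM in running a and 0.565 TPM in sedentary a.

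**Figure D1:**
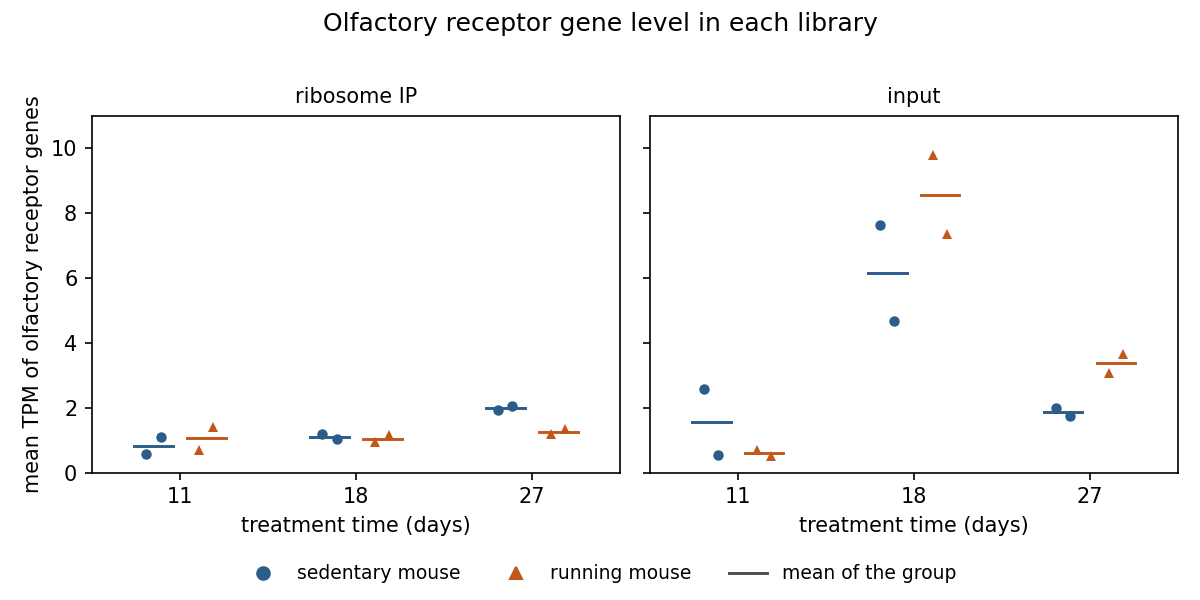
Mean TPM of the olfactory receptor genes in each library (vertical axis) by day, for IP and input libraries, with running and sedentary mice marked apart. The 4 input libraries of day 18 lie between 4.67 and 9.78 TPM, above the other input libraries.

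The comparison of IP with input asked which RNAs the precipitate held above or below their share of the tissue RNA. Some RNAs that are not translated were higher in the IP. Malat1 and Rpph1 took larger shares there, as given above, and the nuclear RNA Xist stood at 467 ± 112 against 78.2 ± 16.8 TPM (SD, n = 12 each). Gm20594 took a smaller share. A rise in the IP therefore need not mean RNA on tagged ribosomes. Genes of neural stem cells, dividing cells, progenitors and newborn neurons rose in the IP. All 16 neural stem cell genes rose. Among them Vim, an intermediate filament gene, stood at 191 ± 57.4 against 42.9 ± 10.7 TPM (SD, n = 12 each, as in all values of this comparison) and the receptor gene Notch1 at 60.3 ± 11.0 against 11.2 ± 2.01 TPM. Of 25 cell cycle genes 24 rose and 0 fell. Top2a, which untangles replicated DNA, stood at 54.3 ± 23.2 against 3.15 ± 0.881 TPM. Of 67 replication-dependent histone genes 56 rose and 4 fell. Of 17 genes of intermediate progenitors and neuroblasts 14 rose and 2 fell. Eomes, a transcription factor of intermediate progenitors, stood at 40.9 ± 18.8 against 2.98 ± 1.51 TPM, Draxin, a guidance protein, at 51.8 ± 17.8 against 3.08 ± 1.21 TPM, and Sox4 at 164 ± 54.0 against 17.2 ± 4.51 TPM. Of 20 immature neuron genes 17 rose and 1 fell. Dcx, which encodes a microtubule protein of migrating neurons (GRCm38 chromosome X, 143855842 to 143933311, minus strand), stood at 119 ± 41.6 against 14.7 ± 1.35 TPM, a log2 difference of 2.86 ± 0.10 (SE, adjusted p = 2.14e-14). Dpysl3 and Dpysl5, growth cone proteins, differed by 3.19 ± 0.09 and 3.31 ± 0.09 on the log2 scale, and the tubulin Tubb2b reached 949.9 ± 264 against 147 ± 33.98 TPM. Of 33 axon guidance genes 24 rose and 2 fell. The semaphorin Sema3c stood at 239 ± 111 against 22.2 ± 4.80 TPM and its receptor gene Plxna2 at 178 ± 32.7 against 47.5 ± 5.86 TPM. Of 31 genes of Notch, Wnt and BMP signalling 17 rose and 4 fell, with Notch2 at 104 ± 20.1 against 15.8 ± 1.42 TPM.

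In camera these lists lay above the other genes, with adjusted p = 1.15e-07 for neural stem cell, 1.9e-10 for cell cycle, 2.37e-10 for histone, 5.7e-06 for progenitor, 4.24e-07 for immature neuron, 4e-05 for axon guidance and 0.0177 for signalling genes. With an estimated correlation the calls of neural stem cell, cell cycle and histone genes held (adjusted p = 0.0436 each), and those of progenitor, immature neuron, axon guidance and signalling genes did not (adjusted p = 0.203, 0.241, 0.361 and 0.527 with an estimated correlation). Adjusted over the list alone, 3 axon guidance genes fell instead of 2, and the counts of the other lists above were the same. Histone genes are near-identical copies, so the value of a single histone gene is uncertain.

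Genes of other cell types fell in the IP. Of 15 interneuron genes 13 fell and 1 rose. The neuropeptide gene Sst (chromosome 16, 23889573 to 23890958, minus strand) stood at 44.4 ± 15.003 TPM in the IP and 350.1 ± 53.0 TPM in the input, a log2 difference of −3.01 ± 0.10 (SE, adjusted p = 5.59e-15). Cck stood at 89.3 ± 16.2 against 317 ± 58.5 TPM, the calcium-binding Pvalb at 4.28 ± 1.62 against 21.04 ± 2.99 TPM, and Gad2, an enzyme that makes GABA, at 22.4 ± 3.97 against 71.2 ± 9.31 TPM. Of 16 microglia genes 14 fell and 1 rose. The protease Ctss stood at 25.4 ± 9.87 against 102 ± 21.1 TPM and the receptor Cx3cr1 at 11.9 ± 2.46 against 24.1 ± 1.75 TPM. Of 16 oligodendrocyte genes 12 fell, with Mal at 14.8 ± 2.54 against 68.5 ± 21.3 TPM, and 1 rose. Of 14 genes of oligodendrocyte precursors 8 fell and 2 rose, with the receptor Pdgfra at 10.6 ± 2.44 against 24.3 ± 2.55 TPM. Of 14 genes of CA pyramidal and mossy neurons 11 fell and 1 rose, with Pcp4 at 263 ± 86.3 against 722 ± 121 TPM. Camera gave adjusted p = 4.43e-07 for interneuron, 2.37e-06 for microglia, 9.98e-06 for oligodendrocyte, 0.00852 for precursor and 0.00101 for pyramidal and mossy neuron genes, and with an estimated correlation adjusted p = 0.0436 for interneuron, microglia, and pyramidal and mossy neuron genes and 0.0451 for the remaining pair. Adjusted over the list alone, the counts of these 5 lists were the same.

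Several mature neuronal and metabolic lists also lay lower in the IP, while genes of glutamate receptors and the postsynapse were not called (12 of 29 rose and 6 fell, the same when adjusted over the list alone, median 0.11, camera adjusted p = 0.776). Of 20 genes of mature granule neurons 14 fell and 4 rose. The vesicle fusion genes stood lower, Snap25 at 526 ± 78.3 against 1480.2 ± 192 TPM and Syt1 at 259 ± 22.99 against 622 ± 128 TPM. Of 23 activity and growth factor genes 13 fell and 6 rose. The opioid precursor Penk stood at 21.2 ± 6.38 against 79.4 ± 31.1 TPM, Nrn1 at 201 ± 26.7 against 555 ± 126 TPM, and the receptor Fgfr1 at 149.8 ± 28.2 against 47.7 ± 5.40 TPM. Of 74 nuclear genes of oxidative phosphorylation 57 fell and 0 rose, with Atp5l at 183 ± 30.2 against 359 ± 42.4 TPM. Of 17 GABA receptor and chloride transport genes 11 fell and 4 rose. Among those that rose, the subunit gene Gabra2 stood at 278 ± 70.6 against 119 ± 23.6 TPM. Of 26 presynaptic genes 14 fell and 8 rose, of 78 cytosolic ribosomal protein genes 37 fell and 5 rose, and of 20 glycolysis genes 14 fell and 1 rose. Camera gave adjusted p = 0.000273 for mature granule neuron, 0.00101 for activity and growth factor, 2.34e-12 for oxidative phosphorylation, 0.000575 for GABA receptor, 0.00755 for presynaptic, 8.52e-05 for ribosomal protein and 0.000931 for glycolysis genes. With an estimated correlation the activity and growth factor call held (adjusted p = 0.0436) and the others did not (adjusted p = 0.153, 0.202, 0.241, 0.241, 0.493 and 0.493 with an estimated correlation, in the order of mature granule neuron, oxidative phosphorylation, GABA receptor, presynaptic, ribosomal protein and glycolysis genes). Adjusted over the list alone, 58 oxidative phosphorylation and 36 ribosomal protein genes fell, and the other counts were the same. Of 18 cholesterol synthesis genes 15 rose and 2 fell (camera adjusted p = 0.0122, and adjusted p = 0.493 with an estimated correlation). Astrocyte genes were not called (8 of 16 rose and 4 fell, camera adjusted p = 0.796), and their median of 0.22 became −0.05 under median-of-ratios scaling.

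The largest ratios of IP to input belonged to a mixed set of genes. Etl4 (chromosome 2, 19909780 to 20810713, plus strand) stood at 4174 ± 1334 against 25.9 ± 4.06 TPM, a log2 difference of 7.22 ± 0.08 (SE, adjusted p = 1.58e-23). Hcfc1, a cofactor of transcription (chromosome X, 73942792 to 73966357, minus strand), stood at 3324 ± 798 against 41.6 ± 6.21 TPM. Sptb, a spectrin of the membrane skeleton, stood at 5465 ± 1519 against 88.6 ± 13.5 TPM, Unc13b, which primes synaptic vesicles, at 364 ± 78.6 against 11.5 ± 0.626 TPM, and Igfbpl1 at 109 ± 34.4 against 3.25 ± 1.36 TPM. The histone genes Hist1h3b, Hist1h2bj, Hist1h2af, Hist1h2bm and Hist1h3g made up the rest of the 10 largest, with log2 differences of 4.88, 4.64, 4.62, 4.46 and 4.24. Among the 10 largest differences below 0 were the small RNA Snora81 (−4.66 ± 0.27) and the RNA of ribonuclease MRP, Rmrp (−2.35 ± 0.24), the neuropeptides Npy (−2.34 ± 0.13), Tac1 (−2.14 ± 0.18) and Adcyap1 (−2.14 ± 0.13), and Apod, Aldh1a1 and Vsnl1 (−2.31 ± 0.14, −2.21 ± 0.08 and −2.12 ± 0.09, SE).

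Genes that check the labels behaved as follows. The tagged gene Rpl22 did not pass, at 148 ± 26.6 TPM in the IP and 159 ± 42.8 TPM in the input (log2 difference −0.08 ± 0.09, adjusted p = 0.413), but fell under median-of-ratios scaling (−0.36, adjusted p = 0.00569). The astrocyte and stem cell filament Gfap rose (409.5 ± 88.6 against 279.9 ± 35.04 TPM, log2 difference 0.52 ± 0.08), and the myelin gene Mbp and the granule neuron gene Calb1 fell (120.3 ± 13.9 against 224 ± 42.7 TPM, and 106 ± 29.6 against 210.1 ± 39.4 TPM). In limma 13631 of 19507 genes passed, 8077 higher (59.3%) and 5554 lower, and 2787 of them differed more than 2-fold. Median-of-ratios scaling moved the median difference of all genes by −0.24, from 0.12 to −0.12, and turned the split to 5423 higher (40.3%) and 8039 lower, so the direction of small differences depends on the scaling. Without the day 18 libraries 10908 genes passed, 7844 of them higher.

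**Figure D2:**
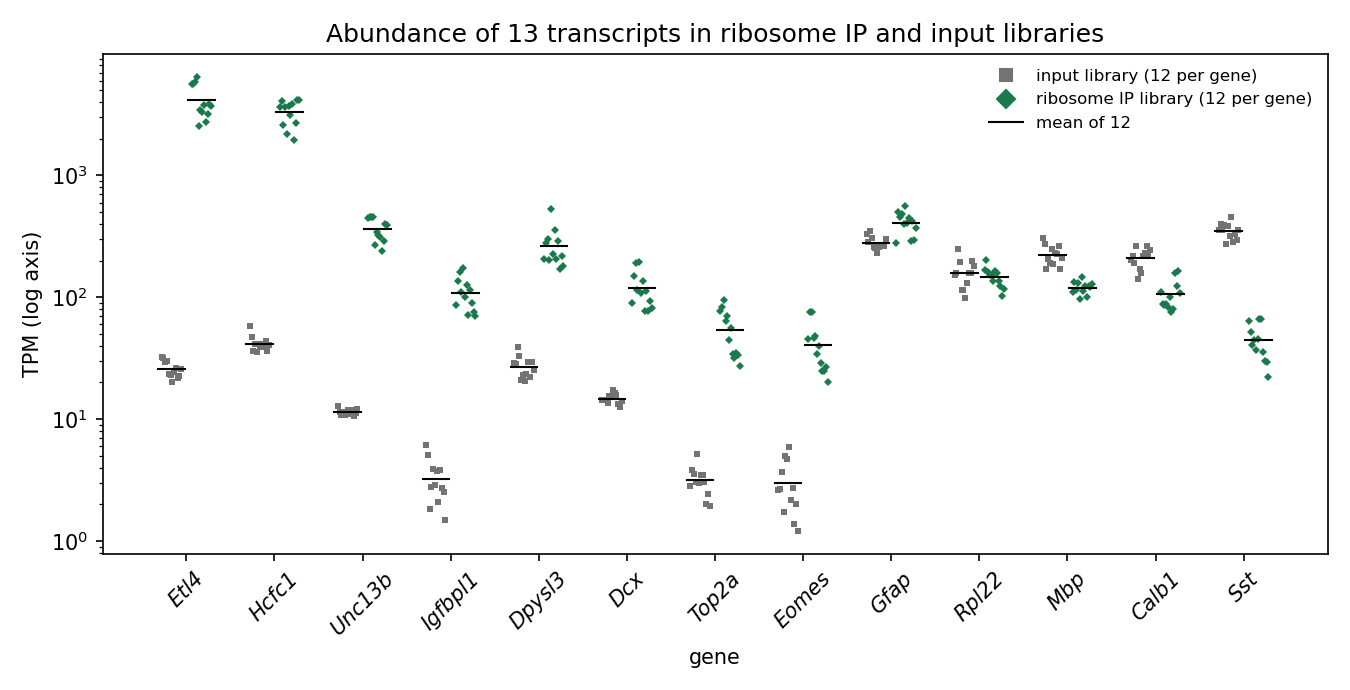
TPM of 13 genes in the 12 IP and 12 input libraries (log axis), 1 point per library, with lines at the means. Dcx, Top2a and Etl4 lie higher in every IP library than in any input library, and Sst lies lower.

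Running against sedentary mice in the IP asked whether exercise changed the RNAs of the precipitate. Over the 3 days, 1 of 17282 genes passed in limma, the small nucleolar RNA Snora16a (chromosome 4, 132309464 to 132309600, plus strand), while 2453 genes had an unadjusted p under 0.05, against 864 by chance. With the library letter as a block, 440 genes passed, 125 higher and 315 lower. Libraries of one letter correlated at 0.24, 0.05 and 0.07 on the 3 days after group means were taken out, and the main fit does not pair them. Whether they are pairs is not known, and the count depends on it. Snora16a stood at 9.05 and 8.62 TPM in running against 18.4 and 18.0 TPM in sedentary mice at day 11, at 4.50 and 4.73 against 4.16 and 5.18 TPM at day 18, and was listed at 0 in both running libraries against 8.80 and 9.36 TPM at day 27 (adjusted p = 0.00105). Several protein-coding genes came near the threshold without passing. Among those higher in running mice were Rgs6, a regulator of G protein signals, at 35.9 ± 6.84 against 21.002 ± 1.12 TPM (SD, n = 6 each, log2 difference 0.73 ± 0.11, adjusted p = 0.0635, and 0.0169 under median-of-ratios scaling), and Inf2, Mylk3, Necab3 and Slc17a6 (log2 differences of 0.60, 0.85, 0.73 and 0.89, adjusted p = 0.0635 for the first 3 and 0.135 for Slc17a6). Among those lower were Thbs4 at 22.2 ± 6.04 against 39.6 ± 8.67 TPM (adjusted p = 0.0635, and 0.0343 under median-of-ratios scaling) and Bcan, Aifm3 and Abca8a (log2 differences of −0.53, −0.61 and −0.84, adjusted p = 0.0635).

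Over the mean of the days, genes of immature neurons lay higher and genes of astrocytes and neural stem cells lay lower in the IP of running mice. No single gene of these lists passed over all genes. Across 17282 genes the running difference correlated weakly between days, so the mean need not stand for each day. Pearson's r was 0.19 for days 11 and 18, −0.17 for 11 and 27 and 0.09 for 18 and 27. Spearman's rho was 0.27, −0.08 and 0.24. All 20 immature neuron genes had a positive difference (median 0.33), and 8 passed when adjusted over the list alone. Calb2, which encodes the calcium-binding protein calretinin of young granule neurons (chromosome 8, 110137502 to 110168210, minus strand), stood at 362 ± 157 against 177 ± 97.6 TPM (log2 difference 1.01 ± 0.20, adjusted p = 0.142). Dpysl3 stood at 317 ± 118 against 211 ± 39.3 TPM (adjusted p = 0.162) and Bhlhe22, a transcription factor, at 277 ± 73.5 against 186 ± 24.02 TPM (adjusted p = 0.161). Of 26 microtubule and growth cone genes 24 had a positive difference (median 0.27), and 9 higher and 1 lower passed when adjusted over the list alone. Map1b stood at 1249 ± 316 against 863 ± 55.6 TPM and Basp1 at 514 ± 117 against 361 ± 25.8 TPM. Of 16 astrocyte genes 1 was positive (median −0.38), and 12 lower passed when adjusted over the list alone. The secreted protein Mfge8 stood at 232 ± 45.2 against 349 ± 69.995 TPM and the gap junction gene Gja1 at 92.4 ± 19.3 against 122 ± 20.1 TPM. Of 16 neural stem cell genes 2 were positive (median −0.24), and 6 lower passed when adjusted over the list alone. Id4 stood at 130.5 ± 19.9 against 177 ± 21.5 TPM, Hopx at 142 ± 22.05 against 187 ± 20.1 TPM and Prom1 at 11.5 ± 2.60 against 16.2 ± 2.22 TPM. Lists of other cell types moved along with them: oligodendrocyte genes (1 of 16 positive, median −0.25) and microglia genes (0 of 16 positive, median −0.21), with 0 members passing when adjusted over the list alone. Interneuron genes (5 of 15 positive, median −0.17), oligodendrocyte precursor genes (2 of 14, median −0.17) and genes of CA pyramidal and mossy neurons (4 of 14, median −0.22) also leaned lower, with 0, 0 and 2 lower members passing when adjusted over the list alone. Of 9 nuclear retained RNAs 0 were positive (median −0.27), and 3 lower passed when adjusted over the list alone. Xist, the RNA that coats the inactive X chromosome, was lower in the running library of each of the 6 letters (log2 difference −0.47 ± 0.14, SE, adjusted p = 0.210, and 0.0198 with the library letter as a block). In the input, Xist was likewise lower in the running library of each letter, from 61.6 against 65.2 TPM in letter a to 53.2 against 73.5 TPM in letter c. The pattern of Xist is therefore not particular to the precipitate.

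In camera the immature neuron and the microtubule and growth cone lists lay above other genes (adjusted p = 1.7e-15 and 1.5e-14) and the astrocyte, neural stem cell, oligodendrocyte and microglia lists below them (adjusted p = 2.1e-06, 0.000103, 0.00522 and 0.0286), as did the nuclear retained RNAs (adjusted p = 0.00101). None of these calls held with an estimated correlation, where all 7 lists had adjusted p = 0.383 with an estimated correlation. The interneuron, precursor, and pyramidal and mossy neuron lists were not called (camera adjusted p = 0.239, 0.177 and 0.211). As levels per library, the immature neuron list had a mean log2(TPM + 1) of 8.02 ± 0.38 in running against 7.66 ± 0.23 in sedentary mice (SD, n = 6 each, two-sided exact permutation p = 0.0741, adjusted p = 0.212). The astrocyte list had 6.54 ± 0.20 against 6.87 ± 0.16 (exact p = 0.0185, adjusted p = 0.122) and the neural stem cell list 5.31 ± 0.27 against 5.54 ± 0.19 (exact p = 0.0370, adjusted p = 0.136). The oligodendrocyte list had 3.79 ± 0.13 against 4.01 ± 0.08 (exact p = 0.00926, the smallest possible, adjusted p = 0.102). The same p and adjusted p held for the interneuron list (4.02 ± 0.15 against 4.15 ± 0.09) and the oligodendrocyte precursor list (3.17 ± 0.04 against 3.31 ± 0.06), and on each day both running libraries lay below both sedentary ones in these 3 lists. The pyramidal and mossy neuron list had 3.95 ± 0.13 against 4.14 ± 0.10 (exact p = 0.0185, adjusted p = 0.122), the microglia list 3.39 ± 0.29 against 3.62 ± 0.13 (exact p = 0.0370, adjusted p = 0.136) and the nuclear retained RNAs 7.81 ± 0.20 against 8.08 ± 0.20 (exact p = 0.0278, adjusted p = 0.131). Without any single library the count of genes over the 3 days lay between 1 and 22, and it was 22 without the running library f of day 27.

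**Figure D3:**
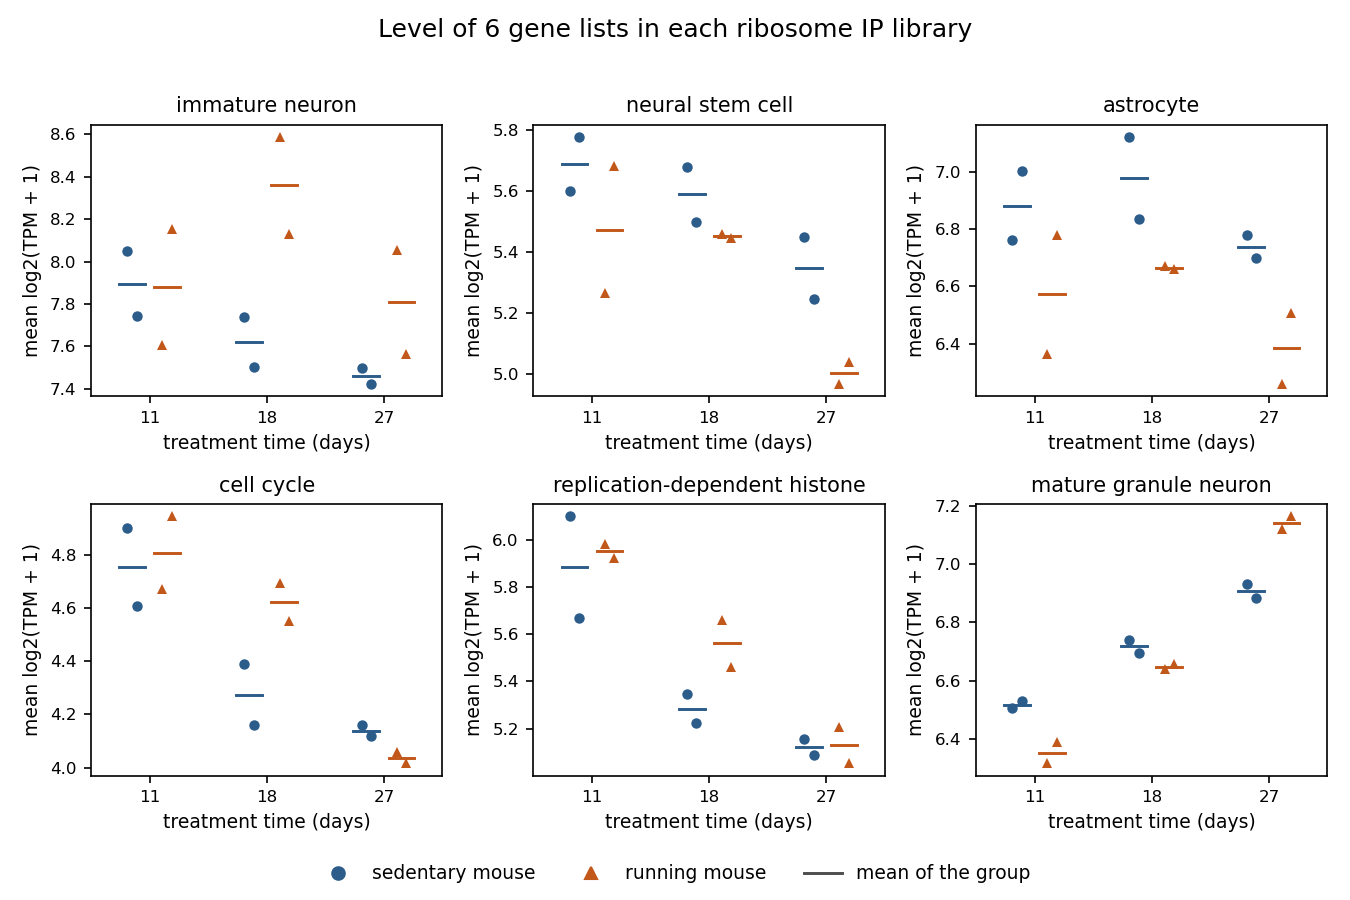
Level of 6 gene lists (mean log2(TPM + 1) of the members, vertical axes) in each IP library by day, with running and sedentary mice marked apart. The immature neuron list averaged 8.02 in running and 7.66 in sedentary mice, and the mature granule neuron list 7.03 at day 27 and 6.43 at day 11.

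Within days, running against sedentary in the IP compared 2 with 2 libraries. At day 18 all 20 immature neuron genes were positive (median 0.73, 15 passing when adjusted over the list alone), with Calb2 at 437 ± 159 against 127 ± 15.6 TPM (SD, n = 2 each, adjusted p = 0.324). At that day 25 of 26 microtubule and growth cone genes were positive (median 0.48, 13 passing when adjusted over the list alone), as were 22 of 25 cell cycle genes (median 0.35, 6 passing when adjusted over the list alone). The spindle protein Tpx2 stood at 39.9 ± 1.22 against 23.7 ± 0.509 TPM and Top2a at 63.3 ± 10.4 against 39.3 ± 7.60 TPM. These 3 lists had camera adjusted p = 3e-18, 3.59e-14 and 6.45e-07, and adjusted p = 0.416 for each with an estimated correlation. Medians of the cell cycle genes were 0.06 at day 11 and −0.06 at day 27, and the list was not tested for a difference between days. At day 11, 15 of 25 were positive (median 0.06, 0 passing when adjusted over the list alone, camera adjusted p = 0.0112, and adjusted p = 0.821 with an estimated correlation), and the list level was lower in running a than in sedentary a (4.67 against 4.90) and higher in running b than in sedentary b (4.95 against 4.61). At day 27, 10 of 25 were positive (median −0.06, 0 passing when adjusted over the list alone, camera adjusted p = 0.899), with levels of 4.06 and 4.02 in running against 4.16 and 4.12 in sedentary mice. At day 11, 7 of 20 immature neuron genes were positive (median −0.05, mean −0.02, with camera on the higher side at adjusted p = 0.366), and the median turned to 0.09 under median-of-ratios scaling, which moved the median of all genes by 0.12 at that day. At day 27, 19 of 20 were positive (median 0.32, camera adjusted p = 1.27e-07, and adjusted p = 0.555 with an estimated correlation), with 0 passing when adjusted over the list alone, and 0 of 16 neural stem cell genes were (median −0.32, 5 lower passing when adjusted over the list alone, camera adjusted p = 6.31e-05, and adjusted p = 0.555 with an estimated correlation). The olfactory receptor background at day 27 was 1.17 and 1.33 TPM in running against 1.93 and 2.05 TPM in sedentary mice. With it as a covariate the neural stem cell median at day 27 was −0.0476 and the astrocyte median −0.0113, against −0.407 for astrocyte genes without it. The immature neuron median was then 0.582 at day 27, 0.708 at day 18 and −0.160 at day 11. At day 27 running and background divide the libraries alike, so the values with the covariate cannot tell them apart.

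At day 27 genes of mature granule neurons and of the presynapse also lay higher in the IP of running mice. Of 20 mature granule neuron genes 16 were positive (median 0.23, 1 passing when adjusted over the list alone). The desmosome gene Dsp stood at 202 ± 3.90 against 125 ± 12.4 TPM (SD, n = 2 each), Calb1 at 161 ± 3.20 against 117 ± 11.5 TPM and the kinase Camk2a at 2163 ± 181 against 1507 ± 183 TPM (adjusted p = 0.307, 0.410 and 0.425). Of 26 presynaptic genes 19 were positive (median 0.26, 3 passing when adjusted over the list alone). The vesicle proteins stood higher, Sv2a at 131 ± 6.78 against 89.2 ± 2.79 TPM and Syn1 at 387 ± 40.9 against 261 ± 28.4 TPM (adjusted p = 0.324 and 0.386). Both lists passed in camera (adjusted p = 3.49e-07 and 1.27e-07) and held with an estimated correlation (adjusted p = 0.0324 and 0.0438). On the other days the mature granule neuron list leaned lower, with 4 of 20 positive at day 11 (median −0.16, 1 lower passing when adjusted over the list alone) and 7 of 20 at day 18 (median −0.07, 0 passing when adjusted over the list alone), and was not called (camera adjusted p = 0.123 and 0.268). Its levels were 6.32 and 6.39 in running against 6.50 and 6.53 in sedentary mice at day 11, and 6.64 and 6.66 against 6.74 and 6.70 at day 18. The presynaptic list had 8 of 26 positive at day 11 (median −0.05, 0 passing when adjusted over the list alone, camera adjusted p = 0.954) and 14 of 26 at day 18 (median 0.09, 1 higher passing when adjusted over the list alone, camera adjusted p = 0.0417, and adjusted p = 0.416 with an estimated correlation).

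Few single genes passed within a day. In limma 0 genes passed at day 11 (832 at an unadjusted p under 0.05), 0 at day 18 (1550) and 5 at day 27 (1714), and with the library letter as a block 1, 18 and 47. The 5 were Mir326, at 11.2 ± 1.16 TPM in running mice and listed at 0 in both sedentary libraries (adjusted p = 0.00304), as well as Snora16a (adjusted p = 1.89e-05), Mir690, listed at 0 in both running libraries and at 6.05 ± 0.269 TPM in sedentary mice (adjusted p = 0.0363), and 2 lower gene models without proper names. The running effect differed between days for 1 gene, Snora16a, by the F test, with 934 genes at an unadjusted p under 0.05, and for 36 genes with the block.

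The running effect in the IP was set against that in the input, to ask whether precipitate and tissue moved differently. In limma 0 genes passed, and 1166 had an unadjusted p under 0.05. Among the genes of low p were Calb2 and Rgs6 in the higher direction (difference of log2 differences 1.13 ± 0.24 and 0.74 ± 0.16, SE) and Ccdc8, Plin5 and Irf8 in the lower one (−1.02 ± 0.20, −1.40 ± 0.29 and −1.18 ± 0.26), each with adjusted p = 0.595. Of 20 immature neuron genes 19 were positive (median 0.32), of 26 microtubule and growth cone genes 25 (median 0.26) and of 16 astrocyte genes 1 (median −0.23). Camera gave adjusted p = 4.49e-10, 4.49e-10 and 0.00348 for these lists, and adjusted p = 0.449, 0.449 and 0.506 with an estimated correlation. Adjusted over the list alone, 1 immature neuron gene passed and no gene of the other 2 lists did.

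Day against day in the IP asked how the RNAs of the precipitate changed over the treatment time. From day 11 to day 27, genes of division and of progenitors fell and genes of mature granule neurons and of the postsynapse rose. Of 25 cell cycle genes 19 fell and 1 rose. Top2a (chromosome 11, 98992943 to 99024189, minus strand) stood at 31.9 ± 3.33 TPM at day 27 and 79.8 ± 12.9 TPM at day 11 (SD, n = 4 each, as in all values of this comparison, log2 difference −1.29 ± 0.14, adjusted p = 0.000103). Tpx2 stood at 18.0 ± 1.67 against 47.6 ± 7.30 TPM, Ube2c at 10.3 ± 3.17 against 27.8 ± 5.94 TPM and Cenpf at 16.7 ± 0.595 against 37.9 ± 5.57 TPM. Of 64 histone genes 36 fell and 0 rose. Hist1h3b stood at 55.0 ± 5.97 against 134 ± 30.98 TPM and Hist1h2af at 105 ± 7.56 against 237 ± 44.4 TPM. Of 16 progenitor and neuroblast genes 9 fell. Eomes stood at 24.2 ± 2.88 against 60.8 ± 17.4 TPM, Insm1 at 9.83 ± 1.79 against 19.4 ± 2.84 TPM, Elavl4 at 13.9 ± 1.32 against 26.7 ± 4.42 TPM and Neurod4 at 3.27 ± 0.995 against 9.66 ± 2.92 TPM. Of 16 neural stem cell genes 5 fell. Vim stood at 125 ± 33.3 against 242 ± 32.5 TPM and Sox1 at 34.7 ± 4.38 against 55.7 ± 9.58 TPM. Of 20 immature neuron genes 4 fell and 1 rose, with Calb2 at 157 ± 60.2 against 370.1 ± 126 TPM. Of 78 ribosomal protein genes 29 fell and 1 rose, with Rpl14 at 301 ± 60.4 against 576 ± 102 TPM and Rps26 at 397 ± 73.0 against 657 ± 106 TPM. Some lists of cell types depleted in the IP also leaned lower over these days. Of 16 microglia genes 3 fell and 0 rose (median −0.41), of 15 interneuron genes 2 fell and 1 rose (median −0.18), and of 16 oligodendrocyte genes 0 passed (3 positive, median −0.19), the same when adjusted over the list alone. Camera gave adjusted p = 9.4e-06, 0.00243 and 0.00182, and adjusted p = 0.151, 0.108 and 0.228 with an estimated correlation. As levels, microglia genes had 3.33 ± 0.17 against 3.71 ± 0.06 and interneuron genes 3.95 ± 0.13 against 4.18 ± 0.06, with every library of day 27 below every library of day 11 (two-sided exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0786).

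Of 20 mature granule neuron genes 13 rose and 0 fell from day 11 to day 27. Icam5, an adhesion molecule of dendrites (chromosome 9, 21032073 to 21039036, plus strand), stood at 181 ± 31.7 against 82.7 ± 11.8 TPM (n = 4 each, log2 difference 1.12 ± 0.11, adjusted p = 7.27e-05). The synaptic organisers C1ql2 and C1ql3 stood at 107 ± 28.3 against 44.9 ± 7.22 TPM and 143 ± 22.2 against 83.0 ± 9.08 TPM, and Plk5 at 28.3 ± 1.88 against 14.4 ± 5.44 TPM. Of 29 glutamate receptor and postsynaptic genes 16 rose and 0 fell. The receptor Grm2 stood at 94.4 ± 21.1 against 46.6 ± 4.15 TPM and the receptor Grin1 at 329.6 ± 58.5 against 178 ± 4.73 TPM, and the kinases Camk2a at 1835 ± 407 against 934 ± 58.6 TPM and Camk2b at 796 ± 209 against 411 ± 40.0 TPM. The 10 largest rises were those of Xkrx, Olfr547, Arl9, Tmem254a, Ncdn, Cryaa, Fstl4, Cdhr1, Slc8a2 and Fam89a. Xkrx stood at 249.7 ± 76.2 against 56.8 ± 15.3 TPM, Ncdn, a neuronal cytoplasmic protein, at 984 ± 285 against 358 ± 47.7 TPM, and the sodium-calcium exchanger Slc8a2 at 304 ± 92.0 against 112 ± 8.78 TPM. Besides histone genes and Ube2c, Tpx2 and Neurod4, the largest falls were those of Snord15a (−2.08 ± 0.43), the kinetochore genes Nuf2 and Spc25 (−1.58 ± 0.18 and −1.43 ± 0.20), Lgals1 (−1.37 ± 0.19) and the chromatin protein Hmgb2 (−1.34 ± 0.17, SE).

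For day 27 against day 11, camera gave adjusted p = 2.64e-22 for cell cycle, 2.06e-31 for histone, 6.68e-13 for progenitor, 9.93e-10 for neural stem cell, 0.00028 for immature neuron, 2.93e-24 for ribosomal protein, 5.46e-10 for mature granule neuron and 1.89e-06 for glutamate receptor and postsynaptic genes. With an estimated correlation the histone and mature granule neuron calls held (adjusted p = 0.0412 and 0.0130), and the others did not (adjusted p = 0.108 for cell cycle, 0.542 for immature neuron and 0.228 for the other 4 lists with an estimated correlation). Adjusted over the list alone, 22 cell cycle, 43 histone, 11 progenitor, 7 neural stem cell, 5 immature neuron and 45 ribosomal protein genes fell, and 16 mature granule neuron and 17 glutamate receptor and postsynaptic genes rose, with 1 cell cycle, 2 histone, 1 immature neuron and 2 ribosomal protein genes going the other way. In limma 2642 genes passed, 1971 higher (74.6%) and 671 lower. Median-of-ratios scaling moved the median of all genes by −0.12 and gave 1328 higher (47.4%) and 1471 lower. The olfactory receptor background also differed between these days, at 1.62 ± 0.432 against 0.944 ± 0.380 TPM, and with it as a covariate 85 genes passed, 72 higher and 13 lower. As this background follows the first principal component of the IP (0.811), the covariate may also remove change with the days of other causes. Without both day 11 libraries of letter a, 636 passed, and without single libraries between 1014 (sedentary a of day 11 left out) and 4185 (running b of day 11 left out).

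The steps between neighbouring days were smaller. From day 11 to day 18, 978 genes passed in limma, 788 higher (80.6%) and 190 lower, against 473 higher (50.2%) and 469 lower under median-of-ratios scaling, which moved the median of all genes by −0.10. Xkrx stood at 154 ± 57.1 against 56.8 ± 15.3 TPM (SD, n = 4 each), Pik3r5, a subunit of a lipid kinase, at 29.1 ± 1.43 against 11.5 ± 3.04 TPM, Cers1, a ceramide synthase, at 51.1 ± 1.77 against 26.2 ± 4.77 TPM. Lrrc26, Npff and Runx3 rose by log2 differences of 1.26, 1.15 and 1.03. Cdr1 stood at 1967 ± 158 against 4450.0 ± 591 TPM, the actin-binding Tmsb4x at 360.2 ± 83.4 against 782 ± 113 TPM. Lsm5, Snora16a, Mgst1 and Hist1h2ao had log2 differences of −1.58, −1.29, −1.27 and −1.13. Of 25 cell cycle genes 7 fell (12 when adjusted over the list alone, with 1 higher) and of 64 histone genes 13 fell (24 adjusted over the list alone). Of 78 ribosomal protein genes 11 fell (28 adjusted over the list alone, with 1 higher), and of 20 mature granule neuron genes 6 rose (11 adjusted over the list alone). Camera gave adjusted p = 2.1e-11, 1.77e-22, 1.17e-24 and 0.00661 for these lists, and adjusted p = 0.423, 0.192, 0.429 and 0.267 with an estimated correlation. No gene passed without both day 11 libraries of letter a, and leaving out any single library of these days gave between 131 (sedentary a of day 11) and 2679 (running b of day 11).

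From day 18 to day 27 in the IP, 21 genes passed in limma, 12 higher and 9 lower, with 2293 at an unadjusted p under 0.05. The calcium-binding Calb1 stood at 139 ± 26.6 against 85.1 ± 11.1 TPM (SD, n = 4 each, adjusted p = 0.0339), the phosphatase Ptprj at 148 ± 30.9 against 88.0 ± 5.73 TPM and the calcium sensor Ncald at 281 ± 55.7 against 176 ± 15.5 TPM. Sowaha, Ets2, Arhgef3, Hpcal4 and Gucy1b3 rose by log2 differences of 0.67, 0.67, 0.66, 0.60 and 0.60. Vim stood at 125 ± 33.3 against 206 ± 19.1 TPM and the membrane linker Ezr at 123.3 ± 23.3 against 224 ± 20.002 TPM. Hist1h3b, Kcne1l, Acot1, Lmnb1, Tpx2 and Ruvbl2 had log2 differences of −1.15, −0.96, −0.84, −0.78, −0.75 and −0.72. Of 20 mature granule neuron genes 1 rose (12 when adjusted over the list alone), 18 were positive (median 0.38), and camera gave adjusted p = 1.04e-10, and adjusted p = 0.00958 with an estimated correlation. The count of genes was 0 without running library c, sedentary library d of day 18 or sedentary library f of day 27, and 112 without running library e of day 27.

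Running against sedentary in the input asked about the whole tissue. In limma 0 of 20462 genes passed over the 3 days, and 858 had an unadjusted p under 0.05, against 1023 by chance. The gene of lowest p was Mylk3, a myosin light chain kinase (chromosome 8, 85324303 to 85386345, minus strand), at 17.5 ± 2.51 against 7.83 ± 1.56 TPM (SD, n = 6 each, log2 difference 1.07 ± 0.13, adjusted p = 0.118). Next among those higher were the synaptic pentraxin Nptx2 at 24.1 ± 3.27 against 15.2 ± 3.33 TPM, Penk at 97.2 ± 33.9 against 61.6 ± 14.8 TPM and Tnnt2 at 17.5 ± 8.10 against 7.37 ± 2.55 TPM (adjusted p = 0.619, 0.762 and 0.774). Among those lower were the clock-controlled transcription factor Hlf at 59.1 ± 12.8 against 90.3 ± 13.6 TPM, Prr16, Vwa3a and the nitric oxide synthase Nos1 (log2 differences of −0.62, −0.61, −0.59 and −0.53, adjusted p = 0.774, 0.762, 0.762 and 0.926). The immature neuron list was not called in the input (12 of 20 positive, median 0.04, camera adjusted p = 0.310). Within days, 0 genes passed at day 11 (500 at an unadjusted p under 0.05), 2 at day 18 (1210) and 0 at day 27 (1079), and 0 in the F test across days (1015). At day 18 these were Scarna8, at 9.54 ± 0.148 TPM in running mice and listed at 0 in both sedentary libraries (adjusted p = 0.00756), and Mir701, listed at 0 in both running libraries and at 7.83 ± 2.11 TPM in sedentary mice (adjusted p = 0.0155).

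Day against day in the input, the steps to and from day 18 gave the largest counts next to IP against input. From day 11 to day 18, 10074 genes passed in limma, 7736 higher (76.8%) and 2338 lower, and 6238 of them differed more than 2-fold. The largest rises were those of genes that belong to other tissues or to repeated families. The vomeronasal receptors Vmn1r148 and Vmn2r42 stood at 23.4 ± 5.10 against 1.65 ± 2.85 TPM and 41.7 ± 8.99 against 4.53 ± 6.04 TPM (SD, n = 4 each). The urinary protein Mup2 stood at 21.7 ± 9.54 against 1.74 ± 2.91 TPM, the hormone Prl2c2 at 27.3 ± 9.61 against 2.25 ± 3.16 TPM, the hair protein Krtap20-2 at 17.8 ± 8.12 against 0.995 ± 1.26 TPM. Mir680-2 stood at 371 ± 116 against 36.3 ± 25.9 TPM and the major histocompatibility gene H2-Q4 at 4822 ± 861 against 578 ± 500.3 TPM. Such family members share sequence, so single values are uncertain. Neuronal genes were among the falls. Calmodulin Calm2 stood at 2757 ± 737 against 7116 ± 2961 TPM and the granule protein Chgb at 456 ± 113 against 1123 ± 422 TPM. Smim11, Pfdn4, Tgoln2 and Hypk had log2 differences of −1.41, −1.36, −1.30 and −1.27. Of 74 oxidative phosphorylation genes 32 fell, of 78 ribosomal protein genes 29 fell and of 20 immature neuron genes 13 fell, none of these lists having a higher call, and of 10 choroid plexus and ependyma genes 7 rose. Camera gave adjusted p = 1.67e-12, 1.32e-10, 1.55e-06 and 0.0407, and adjusted p = 0.125, 0.195, 0.125 and 0.371 with an estimated correlation, and adjusted over the list alone the counts were 31, 28, 13 and 7. Median-of-ratios scaling moved the median of all genes by −0.12 and gave 7268 higher (64.5%) and 3995 lower. The majority turned under quantile normalization, with 1852 higher and 2643 lower of 4495 genes, and with a mean TPM of at least 5, with 1508 higher and 1899 lower of 3407. With the olfactory receptor background as a covariate 0 passed. That covariate ran almost along the first principal component of the input (correlation 0.996 in absolute value). It therefore also removes day differences of other causes that follow this component, and the 0 does not single out background.

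From day 18 to day 27 in the input, 7592 genes passed in limma, 2134 higher (28.1%) and 5458 lower. With a mean TPM of at least 5 the majority turned, with 1467 higher and 889 lower of 2356 genes. Gcm1 stood at 117 ± 29.9 against 708 ± 192 TPM (SD, n = 4 each), Prl2c2 at 3.35 ± 2.48 against 27.3 ± 9.61 TPM, the pigment cell gene Mlana at 0.552 ± 1.10 against 6.81 ± 1.12 TPM and Olfr362 at 0.723 ± 0.441 against 9.50 ± 4.37 TPM. The respiratory chain gene Ndufb4 rose from 409 ± 194 to 856 ± 72.4 TPM, the chromatin protein Dek from 93.5 ± 24.5 to 207 ± 38.2 TPM and Mbd2 from 78.8 ± 25.4 to 169 ± 22.2 TPM. Of 20 mature granule neuron genes 9 rose (10 adjusted over the list alone, camera adjusted p = 5.97e-06, and adjusted p = 0.368 with an estimated correlation) and of 10 choroid plexus and ependyma genes 4 fell (7 adjusted over the list alone, camera adjusted p = 0.0167, and adjusted p = 0.398 with an estimated correlation). Leaving out sedentary library c of day 18 left 1810 genes, and with the olfactory receptor background as a covariate 0 passed. The 0 with the covariate has the limit given for the step from day 11 to day 18. Between day 27 and day 11 in the input 0 genes passed in limma, with 2917 at an unadjusted p under 0.05. Among the genes of low p were Mir680-2 in the higher direction (log2 difference 2.02 ± 0.27, adjusted p = 0.0805) and Lars2, at 874 ± 126 against 2211 ± 908 TPM (adjusted p = 0.0805), and the activity gene Arc, at 18.3 ± 2.37 against 27.3 ± 1.25 TPM (adjusted p = 0.0864), in the lower one. Without sedentary library a of day 11, 1380 genes passed, 1371 of them higher.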

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

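No test of this part was chosen after the result was seen. The effect of running on Snora16a, a small nucleolar RNA, differed between days in the IP (limma F test of the difference between days, adjusted p = 0.00702). Its log2 difference between running and sedentary mice rests on libraries listed at 0 at day 27, so no fold is given for that day. At day 11 it stood at 9.05 and 8.62 TPM in running against 18.4 and 18.04 TPM in sedentary mice, and at day 18 at 4.50 and 4.73 against 4.16 and 5.18 TPM. At day 27 it was listed at 0 in both running libraries and at 8.80 and 9.36 TPM in both sedentary ones. In the input, the running libraries of day 27 held 18.2 and 7.47 TPM and the sedentary ones 26.5 and 3.41 TPM. The transcript is short and low in TPM, and with 2 libraries in each group and no read depth a value of 0 cannot be weighed against chance, so no explanation was tested.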

How the results depend on the processing

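Tests chosen after the data were seen were those with the background covariate, without the day 18 libraries, without both day 11 libraries of letter a, with days 18 and 27 alone, and the list tests by quantile normalization, without structural RNA genes and without single libraries. For IP against input, the count of 13631 genes stayed within 1.5 times under every alternative run, between 9688 and 14896, and between 12707 and 13722 without single libraries. The running effect in the IP minus that in the input had 0 genes in limma under every alternative run except without single libraries, where it had 0 to 1, the 1 coming without sedentary c or running d of day 18. Unless a construction is named, the cause was not tested for any change below.

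For running in the IP over the days (1 gene), counts were 5 with a pseudocount of 5, 11 with a mean TPM of at least 5, 3 with median-of-ratios scaling, 4 with quantile normalization, 0 without structural RNA genes, which leave out Snora16a itself, 3 with array weights, 6 with day as an additive term, 2 with the background covariate, and 0 without both day 11 libraries of letter a or from days 18 and 27 alone. Without single libraries it was 1 to 22: 22 without running f of day 27, 6 without running b of day 11, 4 without sedentary c and 3 without running d of day 18, and 2 without running c of day 18, sedentary e or sedentary f of day 27. For day 11 (0 genes), the 4 libraries of the day alone gave 14, and the range without single libraries was 0 to 2, with 2 without running c of day 18. For day 18 (0 genes), counts were 1 with a pseudocount of 0.1, 1 with array weights, 9 from the 4 libraries alone, 6 with the covariate and 2 without both libraries of letter a, and 0 to 9 without single libraries, with 9 without sedentary c. For day 27 (5 genes), counts were 1 with a pseudocount of 0.1, 2 with a mean TPM of at least 5, 3 with quantile normalization, 0 without structural RNA genes, 0 from the 4 libraries alone, 2 with the covariate and 1 relative to the input, and 2 to 15 without single libraries, with 15 without running e. For the difference between days in the IP (1 gene), counts were 2 with a pseudocount of 5, 3 with no filter, 0 without structural RNA genes, 2 with the covariate and 2 relative to the input, and 1 to 7 without single libraries, with 7 without sedentary c of day 18.

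With the library letter as a block, which takes a running and a sedentary library of one letter as a pair, running in the IP gave 440 genes (125 higher, 315 lower) over the days, 1 at day 11, 18 at day 18, 47 at day 27 and 36 for the difference between days, and running in the input at day 18 gave 0. After group means were taken out, libraries of one letter correlated across genes at 0.24, 0.05 and 0.07 on days 11, 18 and 27 in the IP and at 0.26, 0.09 and 0.08 in the input. IP and input libraries of one code correlated at −0.05, −0.01 and −0.03 in running and −0.28, −0.01 and −0.01 in sedentary mice. These last values do not show whether running and sedentary libraries of one letter belong together. At day 11 the IP libraries of letter a lay at −49.7 and −42.1 on the first principal component, against −5.52 and −4.88 for letter b. On days 18 and 27 the letters overlapped on it. The main fit did not take the letters as pairs. Whether they are pairs stays open, and with it whether 1 or 440 genes pass for running in the IP.

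Day 18 against day 11 in the IP (978 genes) gave 0 without both day 11 libraries of letter a and 131 to 2679 without single libraries: 131 without sedentary a, 347 without running a, 2679 without running b and 557 without sedentary b of day 11, and 409, 392, 246 and 280 without running c, sedentary c, running d and sedentary d of day 18. Day 27 against day 11 in the IP (2642 genes) gave 85 with the covariate, 636 without both libraries of letter a and 1014 to 4185 without single libraries: 1602 without running a, 1014 without sedentary a and 4185 without running b of day 11, and 1268, 1574 and 1237 without sedentary e, running f and sedentary f of day 27. Day 27 against day 18 in the IP (21 genes) gave 37 with a pseudocount of 5, 55 with a mean TPM of at least 5, 112 with quantile normalization, 66 without structural RNA genes, 172 with array weights, 5 with the covariate and 37 without both libraries of letter a. Without single libraries it was 0 to 112: 0 without running c or sedentary d of day 18 or sedentary f of day 27, 112 without running e, 2 without sedentary e and 5 without running f of day 27, 10 without running d of day 18, and 78 without running a or running b of day 11.

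In the input, running over the days (0 genes) gave 1 with day as an additive term and 0 to 2 without single libraries (2 without running d of day 18, 1 without sedentary f of day 27). Day 11 (0 genes) gave 1 with a pseudocount of 0.1, 1 from the 4 libraries alone and 0 to 143 without single libraries, with 143 without sedentary b. Day 18 (2 genes) gave 0 with a pseudocount of 0.1, 4 with a pseudocount of 5, 0 with a mean TPM of at least 5, 1 with quantile normalization, 0 without structural RNA genes, 1 without the robust option and 0 to 8 without single libraries, with 8 without running d. Day 27 (0 genes) gave 1 from the 4 libraries alone and 0 to 1 without single libraries, with 1 without sedentary f. The difference between days (0 genes) gave 1 with a pseudocount of 5 and 0 to 235 without single libraries, with 235 without sedentary b of day 11. Day 18 against day 11 (10074 genes) gave 3407 with a mean TPM of at least 5, which tests fewer genes, 4495 with quantile normalization, 0 with the covariate, and 7512 to 10573 without single libraries. Day 27 against day 11 (0 genes) gave 1.2e+02 with array weights (121 higher and 2 lower) and 0 to 1380 without single libraries: 1380 without sedentary a and 2 without running b or sedentary b of day 11 or sedentary f of day 27. Day 27 against day 18 (7592 genes) gave 3826 with a pseudocount of 0.1, 2356 with a mean TPM of at least 5, 1465 with quantile normalization, 0 with the covariate, and 1810 to 8289 without single libraries: 1810 without sedentary c and 3483 without running c of day 18, and 3812, 4805, 4120 and 2840 without running e, sedentary e, running f and sedentary f of day 27. Each fit without a library that left 1 in its group took its spread from the other groups.

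Of the list tests, 255 passed with the preset and 14 with the estimated correlation, and 235 to 257 passed without single libraries. The list levels per library gave 0 adjusted passes under each alternative run. With the covariate, the log2 differences of Vmn1r148, Vmn2r42 and Krtap20-2 between day 18 and day 11 in the input turned to −0.232, −0.837 and −0.131, and that of Gcm1 between day 27 and day 18 to 0.0627. Relative to the input, the running differences of Mylk3, Penk and Hlf in the IP turned to −0.22, −0.00397 and 0.11, as the input moved as far. The immature neuron list at day 11 in running IP had a median of −0.05, and 0.26 and 0.09 without running a and sedentary a, −0.33 and −0.19 without running b and sedentary b of day 11, and passed in camera without either library of letter a. That list in running input (median 0.04) had medians from −0.0259 without sedentary a of day 11 to 0.055 without sedentary f of day 27, and passed in camera only without sedentary b of day 11 (adjusted p = 0.0302). The glutamate receptor and postsynaptic list in IP against input (median 0.11) turned to −0.1675 under median-of-ratios scaling and was not called in either. The oligodendrocyte precursor list in running IP passed in camera without running a of day 11 (adjusted p = 0.0407). The presynaptic list at day 11 in running IP (median −0.05) turned to 0.07994 under median-of-ratios scaling and to 0.03089 without structural RNA genes, and had medians from −0.13 without sedentary b to −0.008781 without sedentary a of day 11, passing in camera only without running a of day 11. At day 18 it passed in camera (median 0.09), but not under median-of-ratios scaling, quantile normalization or without structural RNA genes. The mature granule neuron list passed in camera, on the lower side, at day 11 without running a and at day 18 under quantile normalization. The cell cycle list at day 11 (median 0.06) had medians from −0.1073 without sedentary b to 0.2229 without sedentary a, and at day 27 (median −0.06) turned to 0.0993 under quantile normalization and had medians from −0.10 without running e to 0.01743 without sedentary e. For the other named genes, 2144 values under alternatives stayed on their side of the threshold, 29 gained and 135 lost the call. For the lists these were 327, 4 and 70. Depth is unknown, so its limit could not be given.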

Other observations

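Tests chosen after the result was seen were those of a purer precipitate, of genes silent in brain, of scaling, of protein length in histone and other genes apart, and with the background covariate by day. Genes of the circadian clock lay lower in running mice. In the input 1 of 16 had a positive difference (median −0.19), and 6 lower passed when adjusted over the list alone, with Hlf at 59.1 ± 12.8 against 90.3 ± 13.6 TPM (SD, n = 6 each), Cry1 at 9.42 ± 1.55 against 13.3 ± 1.02 TPM, Per3 at 20.8 ± 3.39 against 28.6 ± 3.15 TPM and Per2 at 11.7 ± 2.14 against 15.3 ± 1.17 TPM. In the IP 2 of 16 were positive (median −0.20), and 6 lower passed when adjusted over the list alone, with Per3 at 37.7 ± 7.73 against 57.6 ± 7.04 TPM and Hlf at 30.8 ± 5.32 against 43.9 ± 3.42 TPM. In camera the list had adjusted p = 1.21e-07 in the input and 0.00101 in the IP, and adjusted p = 0.399 and 0.383 with an estimated correlation. As a level, the list had 5.17 ± 0.15 against 5.39 ± 0.09 in the input (two-sided exact permutation p = 0.0185, adjusted p = 0.306). The hour at which the mice were taken is not given in the sources used here.

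Activity and growth factor genes in the input of running mice had 15 of 23 positive differences (median 0.04), and 3 higher passed when adjusted over the list alone. Besides Nptx2 and Penk, the growth factors Inhba and Bdnf stood at 24.2 ± 2.95 against 17.7 ± 2.04 TPM and 53.4 ± 7.16 against 43.0 ± 6.50 TPM (SD, n = 6 each), with adjusted p = 0.953. The list was not called by camera (adjusted p = 0.0575). In the IP, 6 of 24 immediate early genes rose from day 11 to day 27 and 0 fell (6 and 0 adjusted over the list alone), with Egr3 at 87.2 ± 18.8 against 35.5 ± 2.24 TPM and Egr1 at 22.1 ± 3.77 against 12.2 ± 1.95 TPM (n = 4 each), and camera gave adjusted p = 0.109. Of 20 glycolysis genes 10 rose and 1 fell, 11 and 1 adjusted over the list alone, with Eno2 at 209.96 ± 34.2 against 114 ± 8.06 TPM (camera adjusted p = 0.0239, and adjusted p = 0.638 with an estimated correlation).

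Genes of immature neurons lay higher in the IP of running mice, with all 20 differences positive and a median of 0.33. A purer precipitate would raise the neural stem cell list as well, since that list was enriched in the IP. That list lay at −0.17 relative to all genes (level of the list, two-sided exact permutation p = 0.0370, adjusted p = 0.136). This leans against a purer precipitate as the whole cause. It does not decide, as the test was chosen after the result was seen and its adjusted p did not pass. Lists depleted in the IP lay lower in running mice, as a purer precipitate would also give. All genes had a median of −0.07, so part of this is a general lean. The oligodendrocyte, interneuron and precursor levels were lower on every day (exact p = 0.00926 each, adjusted p = 0.102), so a part for a purer precipitate stays open. Nuclear retained RNAs, 6 of 9 of which rose from input to IP, also lay lower in running mice (0 of 9 positive). With the olfactory receptor background as a covariate the median of the immature neuron list over the days was 0.35, against 0.33 without, which argues against background of that kind as the cause over the days. By day the covariate moved this median from −0.0470 to −0.160 at day 11, from 0.733 to 0.708 at day 18 and from 0.323 to 0.582 at day 27. It moved that of the neural stem cell list from −0.239 to −0.184 over the days and from −0.317 to −0.0476 at day 27. At day 27 both running libraries held less background than both sedentary ones, so running and background cannot be told apart there. The slope of the covariate came from differences within groups, which were largest between letters a and b of day 11. The value of −0.0476 therefore does not show that the fall of that list follows the background. A purer precipitate in part, a larger share of immature neurons, or more of these RNAs per cell may lie behind the pattern, and the values of −0.17 and 0.35 leave them open. The level of the immature neuron list itself did not pass (two-sided exact permutation p = 0.0741, adjusted p = 0.212).

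The day 18 input libraries stood apart from the other input libraries. Classes of genes silent in brain, other than olfactory receptors, had a median log2 change of 1.72 from day 11 to day 18 over 427 genes, of which 422 were higher and 370 passed. Genes of these classes among the largest rises prompted the test, so 1.72 does not decide whether background reads account for the pattern. Scaling between libraries was not the whole cause, since quantile normalization left 4495 genes, though most were then lower. All 1100 olfactory receptor genes were higher at day 18 than day 11 (mean 7.37 against 1.09 TPM). This argues against a change of the tissue for them. A day's libraries share their handling, so for other genes it was not told apart from such a change.

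The largest ratios of IP to input included Etl4 and Hcfc1, each of which has a protein with 4 residues in a row of the HA tag. Of the 20 genes with the largest ratios 2 had such a stretch, against a mean of 0.312 in random sets matched on protein length, and a share of 0.0357 of 10000 sets had as many. Binding of the nascent protein by the antibody may thus raise these 2 RNAs, and it covers no other gene of the 20. Longer coding sequences were also weighed, since protein length and ratio were related across 16852 genes (Spearman's rho = 0.35), genes not being independent replicates. The 20 genes had a median protein length of 136 residues against 428 for all tested genes. All of the 10000 random sets had a median as large, which argues against length as the cause for the set as a whole. Of the 20, 11 are histone genes of 126 to 136 residues (median 130), and the 9 others had a median of 2090. As these 9 were set apart after that result, by taking out short genes, their length decides nothing for them.

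Other splits of the same libraries were counted with an additive model, so its counts differ from those of the full model. For IP against input the real split gave 12370 genes and the highest of the others 2 (1 of 100 as large). Mixed splits carry the IP difference in their spread, so chance is not excluded. For running in the IP the real split gave 6 genes and 3 of 100 were as large, a share under 0.05, but others gave 7 and 23, the highest. The 23 points to a structure of the samples, and a count as small as 6 is not read as clear of chance. In the IP, 1 of 35 splits was as large for each pair of days. The counts were 1030 against at most 2 genes for day 18 and day 11 and 2723 against 2 for day 27 and day 11. With 35 splits no share can fall below 0.0286, and splits that mix days carry the day difference in their spread. Both counts thus stand out from those of the other splits, but chance is not excluded. The count of the full model for day 18 and day 11 fell from 978 to 0 in limma without both day 11 libraries of letter a, and to between 131 and 557 without any single library of these days except running b of day 11. No other pair of libraries was left out, so this is not shown to be particular to letter a. For day 27 and day 18 they were 5 against 2, and the count of the full model fell to 0 in limma without any of 3 single libraries (2293 at an unadjusted p under 0.05 with all), so this margin is not read as clear of chance. In the input, 1 of 35 splits was as large for day 27 and day 18, with 7814 genes against 1, under the same limit. For day 18 and day 11 in the input 1 of 35 was as large, with 10520 genes, but another split gave 6224, which points to a structure of the samples. Running in the input gave 1 gene, 9 of 100 splits were as large and the highest other gave 2, so chance was not excluded. Where the real split gave 0 genes in limma, every split is as large, so the count says nothing about chance. This holds for day 27 and day 11 in the input (35 of 35, 2917 genes at an unadjusted p under 0.05 in the full model) and for the running effect in the IP minus that in the input (100 of 100, 1166 genes). The highest other splits gave 1253 and 974 genes there, which points to a structure of the samples that was not tested further.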
